A study of Homo sapiens with 16 samples.

How the data were processed

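Gene expression was profiled on Affymetrix Clariom S human arrays in 16 samples of naive CD4 T cells from 4 donors with chronic lymphocytic leukaemia. The 4 groups of 4 samples are DMSO at 3 h, TAK-981 at 3 h, DMSO at 24 h and TAK-981 at 24 h of stimulation through CD3 and CD28. Groups and replicate numbers were taken from the sample titles, and each number stands for 1 donor, per the labels.

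The deposited table holds 1 log2 value per feature and array, made by the authors with SST-RMA, a signal space transformation followed by robust multi-array averaging at the gene level, per the labels. Transcriptome Analysis Console 4.0 and RMA are named in the submitters' processing notes. The log2 scale was inferred from the values. RMA corrects the background, makes the distribution of signals alike on every array and summarises probes, so a change in the total RNA of a cell is removed from these values. The array annotation version, the genome build, scan dates and batches are not given in the sources used here, so no batch could be tested. No detection calls were used here. For arrays the number of samples limits the precision.

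Of 24351 features 2903 controls were set aside and 21448 transcript clusters kept. A table pairing probes with genes named 17709 of them by 1 symbol, and all 17709 matched a RefSeq gene (GRCh38.p14 table, used for names and for the order of genes only) by gene identifier. Clusters of Y-linked genes and of the X inactivation genes were removed before any fit (77 clusters). Of 17 symbols with several probes (36 probes) the probe with the highest mean was kept, which left 21352 clusters to test, 17663 named and 3689 without a single symbol. The 95th percentile of 23 antigenomic control probes, 6.21 on the log2 scale, was taken as background; 12055 clusters had a mean at or below it and were kept, with their removal tried as an alternative by share of mean level. A mean within background is no measured level, so a log2 fold change against it is a difference of signal. None is given for a single gene where all groups compared lay within background. Means of lists include such genes, and lists of mostly dim genes can show little. Correlations between arrays were 0.964 to 0.984 within groups and at least 0.949 for any pair, and no arrays were identical.

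Group means were fitted to all 16 arrays with lmFit of limma 3.58.1 in R 4.3.3, so that the 4 groups shared 1 estimate of the spread. Contrasts were moderated with eBayes, two-sided, and adjusted by Benjamini-Hochberg over all clusters at a threshold of 0.05. The contrasts were TAK-981 against DMSO at 3 h and at 24 h, 24 h against 3 h under each treatment, and the difference between the effects of TAK-981 at 24 h and 3 h. Errors of fold changes are the standard errors of the moderated fit. The donor was not a term of this model, since no source used here states a paired analysis. It entered as a replicate block in an alternative. The standard errors and calls of the main fit therefore leave the pairing by donor out. Donors paired the samples by design; the deviations of same-numbered arrays correlated with r between 0.0735 and 0.276 in 24 pairs, and each of the 24 had its highest correlation with its own number.

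Lists of genes, 42 in all, covering T cell states, SUMO and interferon biology, metabolism, the cell cycle and markers of 7 other blood cell populations, were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation, a correlation of 0.05 and the rotation test fry, which asks whether the genes of a list move on balance one way, were alternatives. List means per array were also compared by exact two-sided permutation of the arrays and, chosen after the data were seen, by flipping the sign of the differences within donors.

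The contrasts, the lists, the alternatives and the rule for naming genes were chosen before the data were examined, apart from a few alternatives added after the data were seen. Of the clusters that passed and moved the same way in 4 of 4 donors, the 8 with the largest rise and the 8 with the largest fall were named for the TAK-981 comparisons, 6 and 6 for time, and 5 and 5 for the difference of effects. Where none passed, the 4 with the lowest p were given as values. Up to 4 passing members of a list were named, or the 2 of highest mean where only the list passed, together with fixed genes of the SUMO pathway and of T cell activation. Genes outside this rule are said to have been chosen after their values were seen.

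The fit was tested on simulated arrays of 21352 clusters, of which 200 were shifted by a known log2 amount. All groups had the means of the DMSO arrays at 3 h, 1 residual SD per cluster and independent noise. The values for 3 h and 24 h are therefore repeat draws of the same setting. Donor effects and unequal spread between groups were left out, so recovery in the real arrays may be lower. At a shift of 1, 28.4% of shifted clusters were recovered for TAK-981 at 3 h and 31.3% at 24 h. At a shift of 2 these shares were 83.6% and 88.1%, and at 3 they were 97.0% for both. There were 7 and 8 false calls. Among 612 negative control features, 23 antigenomic and 63 ERCC features, 0 passed in either TAK-981 comparison, where 28, 0 and 1 had an unadjusted p below 0.05 at 3 h and 27, 0 and 3 at 24 h (limma); 1 antigenomic feature passed for time under DMSO.

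Alternatives were other normalizations (quantile, median centring), removal of the 40% or 20% of clusters with the lowest mean level, moderation with an intensity trend, array weights, a fit of only the compared arrays, the mean of all probes of a gene, a threshold of 2 fold, and leaving out each replicate number or each array. Results were drawn with Python 3.11.15 and matplotlib 3.10.9.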

Results

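Gene expression was measured on 16 Affymetrix Clariom S arrays, 1 per sample, in naive CD4 T cells (CD4+CD45RA+CD45RO-) from the blood of 4 patients with chronic lymphocytic leukaemia, a cancer of B cells. The cells were exposed for 1 h to 1 uM TAK-981 (subasumstat), an inhibitor of the enzyme that activates the small protein modifier SUMO, or to its solvent DMSO. They were then stimulated through CD3 and CD28 with 0.5 ug/mL of antibody, with the compound kept on, and collected after 3 h or 24 h. Each of the 4 groups (DMSO at 3 h, TAK-981 at 3 h, DMSO at 24 h, TAK-981 at 24 h) held 4 arrays, 1 from each donor. Values are log2 signals, so a difference of 1 is a doubling of signal. No unstimulated cells were analysed here, and a change with time is therefore a change between 3 h and 24 h of stimulation.

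The transcriptomes separated by time. The first principal component held 33.1% of the variance and placed the 8 arrays of 3 h between -48.5 and -43.9, with both treatments side by side. The DMSO arrays at 24 h lay between 51.8 and 57.8, and the TAK-981 arrays at 24 h lay below them, at 44.4, 45.7, 16.99 and 42.9. Replicate 3 of the TAK-981 arrays at 24 h held the value of 16.99 and stood apart from the rest of its group. The second component held 9.6% of the variance. In every group it parted replicates 1 and 2, at 5.6 to 51.9, from replicates 3 and 4, at -35.7 to -8.1. No batches are given, so the source of this division could not be tested.

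**Figure D1:**
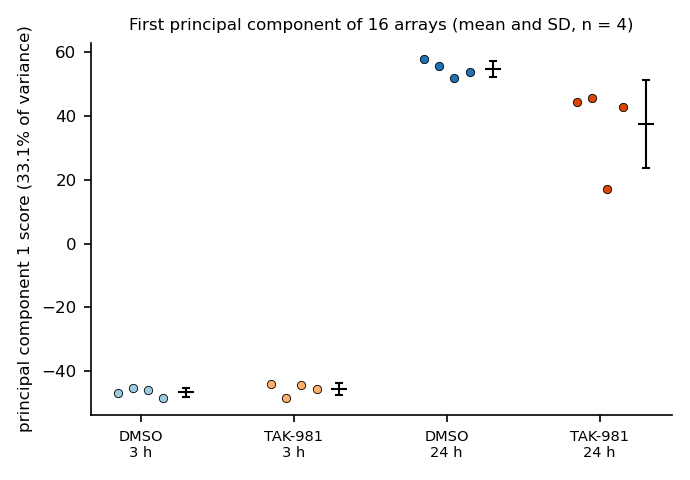
Score of each array on the first principal component of 21352 transcript clusters (y axis, no unit) by group (x axis), with bars for the mean and SD of 4 arrays. All arrays of 3 h lie below -43.9, the DMSO arrays at 24 h lie above 51.8, and 1 of the 4 TAK-981 arrays at 24 h lies at 16.99.

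The course of activation under solvent came from the comparison of DMSO arrays at 24 h and 3 h. Between 3 h and 24 h of stimulation IL2, the gene of the T cell growth factor interleukin-2, rose from 7.23 ± 1.20 to 13.87 ± 0.53 (SD, n = 4 per group), a log2 fold change of 6.64 ± 0.80 (SE). IL2RA, a subunit of its receptor, rose by 3.74 ± 0.33. FOS, NR4A1 and NR4A3, transcription factors induced within an hour of T cell receptor ligation, fell by 4.93 ± 0.31, 4.36 ± 0.48 and 4.75 ± 0.34. Genes of amino acid metabolism, glycolysis and the unfolded protein response rose as groups, and genes of the naive state and of T cell identity fell.

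In total 2706 of 21352 transcript clusters changed with time under DMSO (limma, adjusted p below 0.05), 1548 higher and 1158 lower at 24 h. The other genes with the largest rises were MT1E, a metallothionein (5.66 ± 0.50), GNG8, a G protein subunit (5.34 ± 0.79), WARS1, the tryptophanyl-tRNA synthetase (5.25 ± 0.37), IL12RB2, a chain of the interleukin-12 receptor (5.19 ± 0.88), and IFIT3, an interferon-stimulated gene (5.16 ± 0.68). The other large falls were in GAL3ST4, a sulfotransferase (-5.37 ± 0.51), CRIP1, a LIM domain protein (-5.15 ± 0.50), and RASGRP2, a Rap1 activator (-4.65 ± 0.24). MT1E and IL12RB2 at 3 h and GAL3ST4 and RASGRP2 at 24 h had means within the background range (at or below 6.21), so their fold changes are differences of signal. All of these moved the same way in 4 of 4 donors, which the naming rule required, with limma adjusted p of at most 0.000749.

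**Figure D2:**
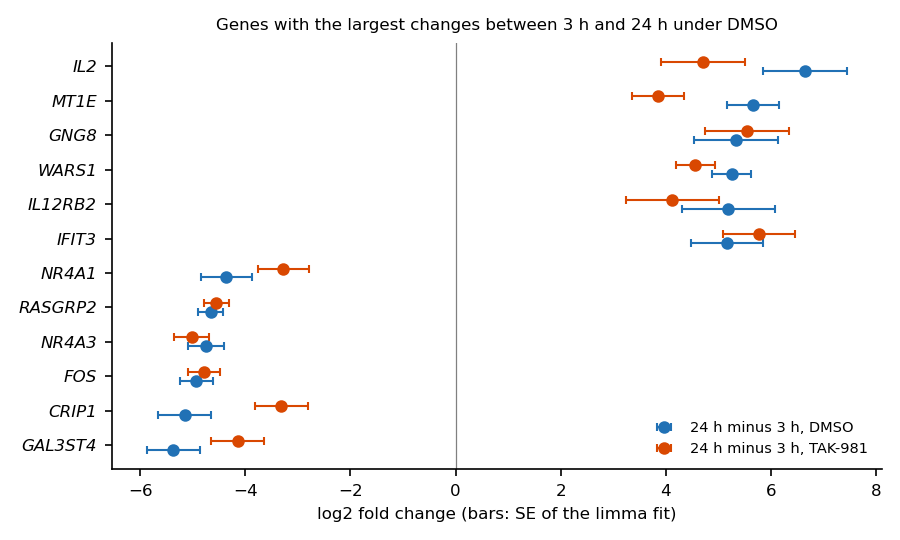
Log2 fold change between 24 h and 3 h (x axis) of the 12 named genes with the largest changes under DMSO (y axis), with bars for the SE of the limma fit, under DMSO and under TAK-981. Each gene moved in the same direction under both treatments, with IL2 at 6.64 under DMSO and 4.71 under TAK-981.

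Of 23 measured genes of ribosome biogenesis and MYC targets, 14 rose, among them SRM, the spermidine synthase (2.79 ± 0.36), and WDR12 (2.45 ± 0.36); 20 were higher and 1 lower when adjusted over the list alone (camera, adjusted p = 2.78e-11, and adjusted p = 0.0821 with an estimated correlation). Of 23 genes of the amino acid stress response and one-carbon metabolism, 12 rose, including SHMT2 (3.28 ± 0.33) and PSAT1 (2.94 ± 0.31), both enzymes of the serine pathway. Adjusted over the list alone, 15 were higher and 1 lower, and the list passed with both kinds of correlation (adjusted p = 2.97e-09 and 0.0344 with an estimated correlation). Of 35 DNA replication genes 16 rose and 0 fell, with CDC6 (2.95 ± 0.53) and GINS2 (2.62 ± 0.58, from within background) as examples. That list had 20 higher members adjusted over the list alone (adjusted p = 5.05e-09, and adjusted p = 0.0830 with an estimated correlation).

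Of 19 glycolysis genes 10 rose and 2 fell. The enzymes ENO1 (1.89 ± 0.18) and PGAM1 (2.07 ± 0.21) rose while the glucose transporter gene SLC2A3 fell by 2.48 ± 0.31 (list adjusted p = 3.61e-06, and 0.0103 with an estimated correlation). Of 19 unfolded protein response genes 11 rose, including the chaperones PDIA6 (2.63 ± 0.45) and HSPA5 (1.28 ± 0.16), with adjusted p = 2.93e-08 for the list and 0.0344 with an estimated correlation. Adjusted over the list alone, 11 glycolysis genes were higher and 2 lower, and 13 unfolded protein response genes were higher. Of 17 heat shock genes 8 rose, such as HSPD1 (1.70 ± 0.20) and STIP1 (1.75 ± 0.19), and 1 fell (adjusted p = 0.000363, and adjusted p = 0.0561 with an estimated correlation). Of 19 cholesterol synthesis genes 8 rose, with FDPS (2.39 ± 0.31) and CYP51A1 (1.77 ± 0.29), and 2 fell (adjusted p = 0.0159, adjusted p = 0.180 with an estimated correlation, and 0.0843 without the 40% of clusters of lowest mean level). Among 13 housekeeping reference genes 3 rose, HPRT1, GAPDH and PGK1 (adjusted p = 0.0202 for the list, and adjusted p = 0.0811 with an estimated correlation). The housekeeping list did not pass without replicate 3 of the DMSO arrays at 3 h (0.0523), with quantile normalization (0.0734) or without the 40% of clusters of lowest mean level (0.0882).

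Of 31 T cell cytokines and chemokines 6 rose, among them LTA, lymphotoxin alpha (3.16 ± 0.35), LIF (2.68 ± 0.42) and IL21 (2.63 ± 0.49), and 1 fell. The list passed at adjusted p = 0.00598, and had adjusted p = 0.286 with an estimated correlation. Without replicate 4 of the DMSO arrays at 24 h its mean went from 0.95 to 0.62 (adjusted p = 0.0674). Of 28 genes of the interferon-gamma response and antigen presentation 12 rose and 2 fell, with CXCL10 at 5.11 ± 1.28, CXCL9 at 4.18 ± 0.93 and CD274, the ligand of PD-1, at 3.27 ± 0.49 (adjusted p = 3.54e-05, and adjusted p = 0.353 with an estimated correlation). The means of CXCL10, CXCL9, LIF and IL21 at 3 h lay within background. Adjusted over the list alone, 14 of the interferon-gamma response genes were higher and 4 lower, and 7 cytokine genes were higher and 2 lower. The 47 type I interferon-stimulated genes did not pass as a list (mean 0.41, adjusted p = 0.187); 6 of them rose, including IFIT3 and IFIT2 (3.97 ± 0.48), and 3 fell, including MX2 (-2.23 ± 0.52).

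Resting-state genes fell. Of 24 genes of the naive and quiescent state 11 fell and 0 rose, among them KLF3 (-3.13 ± 0.23), KLF2 (-2.78 ± 0.37) and IL7R, the interleukin-7 receptor (-3.12 ± 0.45). Adjusted over the list alone, 17 were lower (adjusted p = 4.89e-11, and 0.0165 with an estimated correlation). Of 19 T cell identity genes 11 fell, including CD247 (-2.15 ± 0.35) and CD3G (-1.69 ± 0.19), parts of the T cell receptor complex (adjusted p = 1.61e-06, and 0.0169 with an estimated correlation). Of 47 replication-dependent histone genes 16 fell, with H2AC11 (-2.08 ± 0.27) and H4C5 (-1.81 ± 0.27) as examples (adjusted p = 2.92e-09, and adjusted p = 0.105 with an estimated correlation). Of 17 genes of TGF-beta and SMAD signalling 8 fell, led by SKIL (-3.80 ± 0.36) and SMAD7 (-3.37 ± 0.55), both inhibitors of the pathway, and 1 rose (adjusted p = 3.54e-05, and adjusted p = 0.0561 with an estimated correlation). Among 31 early activation genes 13 fell and 6 rose, BATF among the latter (4.76 ± 0.49) with adjusted p = 0.00939 for the list, and adjusted p = 0.463 with an estimated correlation. It had adjusted p = 0.0514 without replicate 2 of the DMSO arrays at 3 h. Of 19 memory T cell markers 8 fell, CRIP1 among them, and 2 rose (adjusted p = 0.000947, and adjusted p = 0.361 with an estimated correlation).

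SAE1, a subunit of the enzyme that TAK-981 inhibits, rose by 1.07 ± 0.30 with time under DMSO (limma adjusted p = 0.0253), and this call was lost under 9 of 31 other settings. In the SUMO pathway list of 22 genes, DESI1 also rose (2.55 ± 0.27) while SENP7 fell by 2.40 ± 0.32, both SUMO proteases, and the list did not pass (mean 0.09, adjusted p = 0.576). SUMO2 and SUMO3 had values of 0.34 ± 0.19 and 0.26 ± 0.28, which did not pass. Nor did IFNG (0.37 ± 1.60), CD69 (-0.41 ± 0.23), MYC (-0.33 ± 0.31), FOXP3 (0.68 ± 0.33), TBX21 (1.20 ± 0.41), GATA3 (-0.78 ± 0.27) or MX1 (0.99 ± 0.67), nor MKI67 and IFNB1, which lay within background at both times. With the donor as a replicate block TBX21 and GATA3 passed (adjusted p = 0.00345 and 0.02465). The level of IFNG spread widely between donors, with an SD of 3.46 at 3 h under DMSO. The camera test passed 16 of 42 lists for time under DMSO, 10 higher and 6 lower, of which 5 kept an adjusted p below 0.05 with an estimated correlation. Other splits of the same 8 arrays into groups of 4 passed up to 17 lists and at most 3 transcript clusters, and those that parted the arrays of all 4 donors passed up to 14 lists.

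Under TAK-981 the time course involved many of the same genes. Between 3 h and 24 h under TAK-981, 1589 clusters changed, 854 higher and 735 lower. Of the clusters called, 678 were higher under both treatments, where independent lists would share 61.9, and 540 were lower under both, where 39.9 would be shared. IL2 rose by 4.71 ± 0.80 and IFIT3 by 5.76 ± 0.68 under TAK-981.

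Type I interferon-stimulated genes rose with time under TAK-981 as a group: 17 of 47 rose and 0 fell, and 23 were higher when adjusted over the list alone (mean 1.40, camera adjusted p = 2.75e-14, and adjusted p = 0.126 with an estimated correlation). MX1, an antiviral GTPase in that list, rose by 3.37 ± 0.67 under TAK-981. Calls made under 1 treatment and not the other numbered 1487 for DMSO and 370 for TAK-981, which does not test a difference between them. The log2 fold changes of the 2 treatments correlated across clusters with r = 0.748, and with r = 0.527 and 0.596 when the treatments were taken from different donors; clusters are not independent replicates. Of 42 lists 17 passed, 11 higher and 6 lower, and 2 of them, naive and quiescent genes and glycolysis, kept an adjusted p below 0.05 with an estimated correlation.

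After 3 h of stimulation 1 gene passed for TAK-981 against DMSO, in a fit that recovered 28.4% of simulated shifts of 1. NEFM, the gene of the medium neurofilament protein, rose from 4.39 ± 0.17 under DMSO to 7.96 ± 0.40 under TAK-981 (SD, n = 4), a log2 fold change of 3.58 ± 0.31 (SE). The DMSO mean lies within the background range, so this is a difference of signal from background and no exact ratio of transcripts. It was higher in 4 of 4 donors, with limma adjusted p = 4.96e-05. SUMO pathway genes were higher under TAK-981 as a group, by a mean of 0.26 on the log2 scale, and inhibitory receptor genes by a mean of 0.56. These list calls had adjusted p = 0.0953 and 0.581 with an estimated correlation.

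NEFM was called under each of 31 other settings, with adjusted p from 5.1e-06 to 0.00915. The count was 2 without replicate 3 of the TAK-981 arrays at 3 h, 3 without their replicate 4 and 2 without replicate 1 of the TAK-981 arrays at 24 h. In the full fit no other cluster passed, in either direction, while 1278 had an unadjusted p below 0.05 against 1067.6 by chance. The lowest p values among genes lower under TAK-981 belonged to TNFRSF12A, the TWEAK receptor (-1.77 ± 0.36, adjusted p = 0.215), HVCN1, a proton channel (-0.99 ± 0.21, into background), PEDS1 (-1.02 ± 0.21) and NKD1 (-1.25 ± 0.27, into background), none of which passed. Log2 fold changes of the activation and SUMO genes named beforehand also did not pass: SAE1 0.18 ± 0.30, SUMO2 0.06 ± 0.19, SUMO3 0.69 ± 0.28, IL2 -0.08 ± 0.80, IFNG 0.42 ± 1.60, CD69 0.48 ± 0.23 and IL2RA 0.33 ± 0.33. The same held for MYC at -0.53 ± 0.31, FOXP3 at 0.51 ± 0.33, GATA3 at 0.15 ± 0.27 and MX1 at -0.03 ± 0.67, and for TBX21, MKI67 and IFNB1, which lay within background in both groups.

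Of 22 measured SUMO pathway genes 19 had a positive value at 3 h, with a mean of 0.26 ± 0.05 (SD over 4 donors). DESI1 had 0.36 ± 0.27, and 0 members passed over all genes or adjusted over the list alone. The list passed the camera test (adjusted p = 0.00946), and had adjusted p = 0.0953 with an estimated correlation. Of 14 inhibitory receptor genes 10 had positive values, with a mean of 0.56 ± 0.06 (adjusted p = 0.00743, and adjusted p = 0.581 with an estimated correlation). CD200, an immunoregulatory surface protein, had 2.42 ± 0.69 (adjusted p = 0.567) and CD96 had -0.04 ± 0.26. Adjusted over the list alone, 2 members were higher, CD200 and CTLA4, a brake on T cell activation chosen after its value was seen (1.76 ± 0.47). Without replicate 3 of the DMSO arrays at 3 h the SUMO list had adjusted p = 0.0564 and the receptor list 0.0836, and without their replicate 4 the receptor list had 0.101. Neither list passed without the 40% of clusters of lowest mean level (adjusted p = 0.0806 and 0.2745), where their means were 0.26 and 0.58. Other splits of the same 8 arrays passed up to 6 lists, and those that parted all 4 donors up to 1.

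After 24 h a set of genes that included interferon-stimulated genes was higher under TAK-981 than under DMSO. CHAF1B and CKS2, genes of chromatin assembly and of the cell cycle, were lower. CYP4F11, a cytochrome P450 of fatty acid hydroxylation, rose from 3.36 ± 0.11, within the background range, to 8.56 ± 1.95 (SD, n = 4), a log2 difference of signal of 5.20 ± 0.67 (SE). HERC5, the ligase of the interferon-induced modifier ISG15, had 6.28 ± 0.24 under DMSO and 8.76 ± 1.02 under TAK-981. At 3 h its arrays had lain between 6.94 and 7.96 under DMSO and between 7.94 and 8.57 under TAK-981. Part of the HERC5 difference at 24 h is thus a lower DMSO level than at 3 h. PDGFA, a growth factor gene, rose from 4.65 ± 0.20, within background, to 8.20 ± 1.30. CYP4F11, HERC5 and PDGFA spread more under TAK-981 at 24 h than under DMSO. The fit pools the spread over the 4 groups, so its standard errors can be too small for such genes. CHAF1B, a chromatin assembly factor subunit, was lower by 1.49 ± 0.23, at 6.60 under DMSO and within background at 5.10 ± 0.30 under TAK-981. At 3 h its arrays had lain between 4.51 and 5.49 under DMSO and between 5.13 and 5.77 under TAK-981. The CHAF1B difference at 24 h thus goes with a rise over time under DMSO that was not seen under TAK-981. CKS2, a cyclin-dependent kinase subunit, was lower by 1.22 ± 0.21. As groups, type I interferon-stimulated genes were higher under TAK-981, while cytokine, ribosome biogenesis and DNA replication genes were lower, with adjusted p of 0.167, 0.167, 0.250 and 0.330 with an estimated correlation.

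Of 21352 clusters 17 passed at 24 h, 15 higher and 2 lower under TAK-981, and 41 passed with the donor as a replicate block, 33 higher and 8 lower, all 17 among them. The other named rises were in PPP4R4, a regulator of protein phosphatase 4 (3.73 ± 0.63), CNN2, a calponin (2.91 ± 0.47), AFDN, a cell adhesion protein (2.76 ± 0.49), and TRANK1 (2.48 ± 0.36). NID1, a basement membrane protein, was called higher with both means within background, 2.98 under DMSO and 5.39 under TAK-981. Each of these, with CYP4F11, HERC5, PDGFA, CHAF1B and CKS2, moved the same way in 4 of 4 donors, which the naming rule required. Their limma adjusted p lay between 0.0131 and 0.0416. SAMD9, an interferon-stimulated gene, rose by 2.26 ± 0.36. The 6 remaining calls, named after their values were seen to complete the count, were THAP4 (2.30 ± 0.38), ERO1B (2.25 ± 0.36), HPSE (2.10 ± 0.34), BICDL1 (1.72 ± 0.26), BTN3A3 (1.45 ± 0.23) and PHF10 (1.42 ± 0.25). The lower group's mean lay within background for 7 of the 17 genes, CYP4F11, PPP4R4, PDGFA, AFDN, NID1, CHAF1B and HPSE, so the sizes of their changes are not exact ratios of transcripts.

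**Figure D3:**
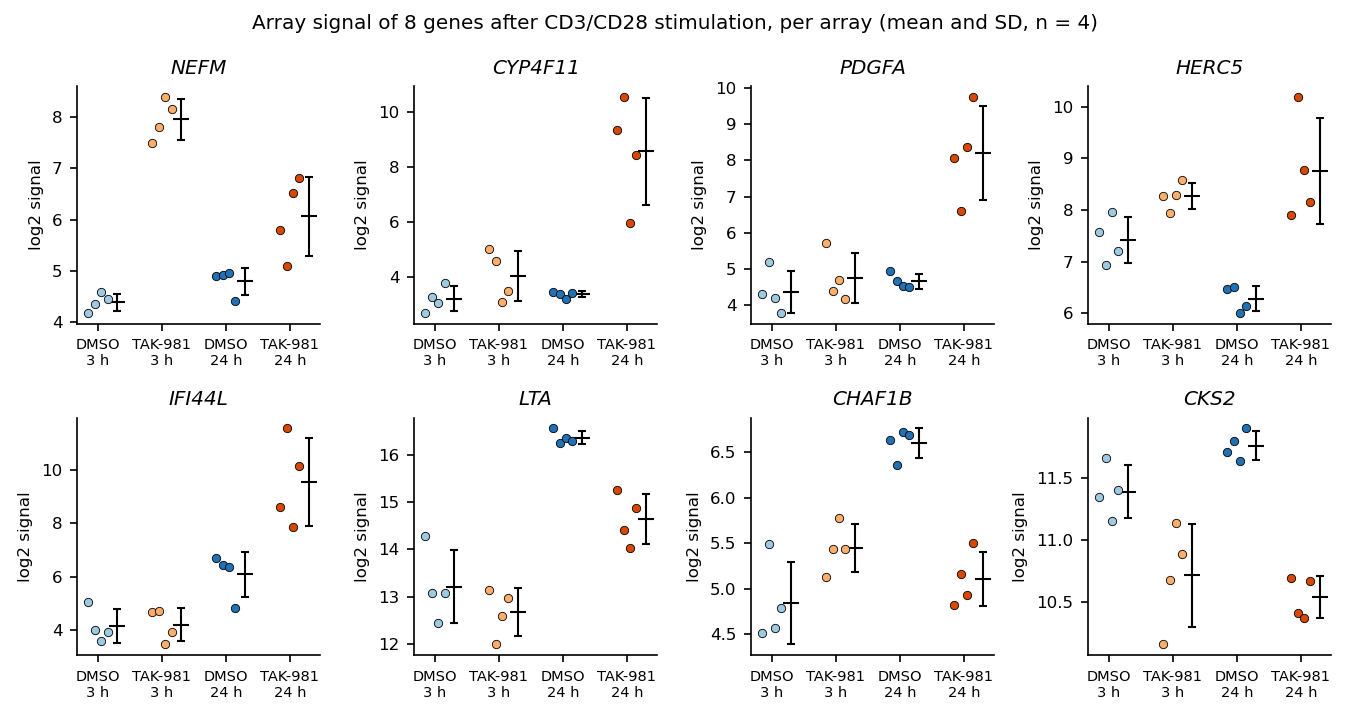
Log2 signal (y axis) of 8 genes in each array by group (x axis), with bars for the mean and SD of 4 arrays. NEFM is highest at 3 h under TAK-981 (mean 7.96), and CYP4F11 and HERC5 are highest at 24 h under TAK-981, with wide spread between donors (SD 1.95 and 1.02).

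The count at 24 h depended on single arrays. It was 0 without replicate 2 of the DMSO arrays at 24 h, 9 without their replicate 3, 6 without their replicate 4, 26 without replicate 2 of the TAK-981 arrays at 24 h and 8 without replicate 3 of them, the array that stood apart. No cluster passed in limma with only the 8 arrays of 24 h in the fit, where 0 replaced 17, and 1416 clusters had an unadjusted p below 0.05 in the fit of 16 arrays. IL2 had -2.02 ± 0.80 under TAK-981 at 24 h, lower in 4 of 4 donors, and did not pass (adjusted p = 0.622). Other values that did not pass were SAE1 at -0.45 ± 0.30, SUMO2 at -0.00 ± 0.19, SUMO3 at 0.49 ± 0.28, IFNG at -1.09 ± 1.60, CD69 at 0.63 ± 0.23, IL2RA at -0.51 ± 0.33 and MYC at -0.68 ± 0.31. The same held for FOXP3 (-0.05 ± 0.33), TBX21 (-0.28 ± 0.41), GATA3 (-0.33 ± 0.27), MX1 (2.35 ± 0.67, adjusted p = 0.345), and for MKI67 and IFNB1, which lay within background in both groups.

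Of 47 measured type I interferon-stimulated genes 44 had a positive value at 24 h. HERC5 and SAMD9 passed over all genes, 5 members passed with the donor as a block, and 20 were higher when adjusted over the list alone. The list mean was 1.03 ± 0.78 (SD over 4 donors), with camera adjusted p = 1.85e-22, and adjusted p = 0.167 with an estimated correlation. The mean was 0.68 without replicate 2 of the TAK-981 arrays at 24 h and 1.26 without their replicate 3. IFI44L, an interferon-stimulated gene chosen after its value was seen, had 3.47 ± 0.63 from within background (adjusted p = 0.0503), and passed with the donor as a block (adjusted p = 0.0244).

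Cytokine and growth genes had lower values. Of 31 T cell cytokines and chemokines 3 had a positive value (mean -0.76 ± 0.24, camera adjusted p = 2.28e-06, and adjusted p = 0.167 with an estimated correlation). LTA had -1.72 ± 0.35, which did not pass (adjusted p = 0.0986) except with the donor as a block (0.0159), and LTB had -0.71 ± 0.29. The cytokine mean was -0.43 without replicate 4 of the DMSO arrays at 24 h, and the list passed there (adjusted p = 0.00604). All 23 ribosome biogenesis genes and MYC targets had a negative value, with NPM1 at -0.10 ± 0.16 and FBL at -0.17 ± 0.20 (mean -0.48 ± 0.27, adjusted p = 1.32e-08, and adjusted p = 0.250 with an estimated correlation). Of 35 DNA replication genes 7 had a positive value, and PCNA had -0.68 ± 0.38 and RRM1 -0.18 ± 0.39 (mean -0.47 ± 0.05, adjusted p = 5.20e-05, and adjusted p = 0.330 with an estimated correlation). Glycolysis genes had a mean of -0.26 ± 0.13, with GAPDH at -0.42 ± 0.20 and PKM at -0.12 ± 0.21 (adjusted p = 0.00294, and adjusted p = 0.127 with an estimated correlation). Without replicate 3 in all groups the glycolysis mean was -0.19 and the list did not pass (adjusted p = 0.0721). Genes of the amino acid stress response had a mean of -0.35 ± 0.19, with SLC7A5 at -0.17 ± 0.34 and SLC38A2 at 0.32 ± 0.24 (adjusted p = 0.00337, and adjusted p = 0.330 with an estimated correlation). Housekeeping reference genes had a mean of -0.16 ± 0.13, lower in 4 of 4 donors, and did not pass as a list (adjusted p = 0.249). No member of the 5 cytokine and growth lists passed over all genes, and adjusted over the list alone 2 cytokine genes, 1 ribosome biogenesis gene and 1 glycolysis gene were lower.

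Genes of the resting state had higher values. Of 24 genes of the naive and quiescent state 17 had a positive value, with CCR7 at 0.34 ± 0.21 and LEF1 at 0.15 ± 0.19 (mean 0.28 ± 0.19, adjusted p = 0.00416, and adjusted p = 0.313 with an estimated correlation). Of 19 T cell identity genes 16 had a positive value, with CD3D at 0.09 ± 0.17 and CD3E at 0.29 ± 0.18 (mean 0.26 ± 0.18, adjusted p = 0.00955, and adjusted p = 0.250 with an estimated correlation). Without replicate 3 of the TAK-981 arrays at 24 h the naive and identity lists had means of 0.15 and 0.17 (adjusted p = 0.225 and 0.276), and without replicate 2 of the DMSO arrays both had 0.0681. Adjusted over the list alone, 1 naive-state gene was higher and 0 identity or Th2 genes passed. The 12 Th2 genes, with IL4R at 0.24 ± 0.30 and STAT6 at -0.24 ± 0.26, had a mean of -0.39 ± 0.26 (adjusted p = 0.0284, and adjusted p = 0.431 with an estimated correlation). The Th2 mean was -0.11 without replicate 4 of the DMSO arrays (adjusted p = 0.381) and -0.22 without replicate 2 of the TAK-981 arrays at 24 h (0.3565), and the list had adjusted p = 0.148 without the 40% of clusters of lowest mean level. In all 9 lists passed, and other splits of the same 8 arrays passed up to 13, or up to 6 where they parted all 4 donors.

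Without regard to donors, an exact two-sided permutation test of each list's mean per array gave p = 0.0286 for interferon-stimulated, ribosome biogenesis and T cell identity genes at 24 h and for SUMO pathway genes at 3 h (n = 4 per group). That is the smallest p these numbers allow, and the Benjamini-Hochberg value over 11 lists was 0.0786. These 11 are the lists that passed camera on the same arrays, so the adjustment does not cover that choice. The exact permutation p was 0.0571 for glycolysis, 0.0857 for amino acid stress and naive genes, 0.114 for cytokines, 0.171 for DNA replication and for inhibitory receptors at 3 h, and 0.371 for Th2 genes. Within donors each of these 11 lists moved in 1 direction in 4 of 4, so the exact two-sided sign-flip p was 0.125 for each, the smallest that 4 pairs allow. Differences between donors are part of the spread in the first test, as for inhibitory receptors, whose mean was higher by 0.51 to 0.65 within donors.

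**Figure D4:**
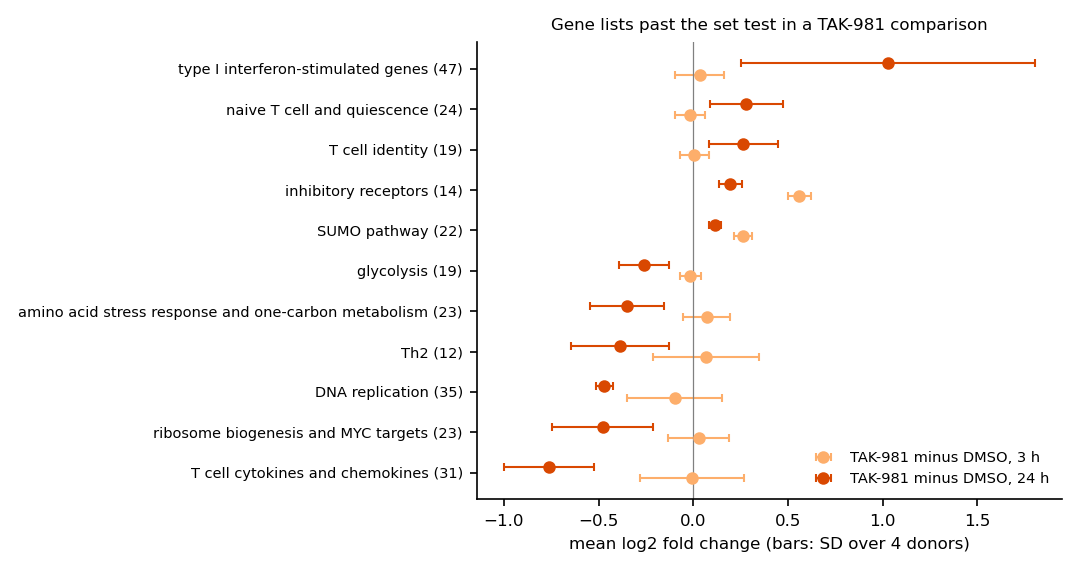
Mean log2 fold change, TAK-981 minus DMSO (x axis), of each gene list that passed the camera test in a TAK-981 comparison (y axis, with the number of measured genes), at 3 h and 24 h; bars are the SD over 4 donors. Interferon-stimulated genes have the highest mean at 24 h (1.03, SD 0.78), and cytokines the lowest (-0.76, SD 0.24).

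Marker genes of other blood cells had small mean values. At 24 h the mean log2 fold change was 0.04 for monocyte and dendritic cell markers, 0.03 for B cell and leukaemia cell markers, -0.03 for NK cells, -0.15 for CD8 and cytotoxic T cells, -0.05 for neutrophils, 0.14 for erythroid cells and platelets and 0.20 for memory T cells. At 3 h these 7 lists had means of -0.11, -0.05, 0.02, -0.09, -0.12, -0.06 and -0.17, in the same order. None passed at either time. The B cell marker list held a gene with high signal in these arrays, FCMR, at 12.53 under TAK-981 at 24 h (0.59 ± 0.32, not passing).

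Whether the effect of TAK-981 changed between 3 h and 24 h was asked with the interaction of compound and time. No cluster passed this test of the difference, with or without the donor as a block, and 1147 had an unadjusted p below 0.05 in limma. Gene groups did pass the camera test: interferon-stimulated genes had a larger mean effect at 24 h than at 3 h, by 1.00 ± 0.68 (SD over 4 donors) and by 0.65 without replicate 2 of the TAK-981 arrays at 24 h, and 5 groups of growth and cytokine genes a lower one. Each of the 6 had an adjusted p of at least 0.463 with an estimated correlation. The count of clusters was 1 without replicate 2 of the DMSO arrays at 3 h (CHAF1B) and 1 without replicate 3 of the TAK-981 arrays at 24 h (CYP4F11).

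The lowest p values for a larger effect at 24 h were those of NID1 (adjusted p = 0.198), which lay within background in all 4 groups, HPSE (2.38 ± 0.48), CYP4F11 (4.37 ± 0.95) and B3GNT5 (2.38 ± 0.53). In the other direction they were those of CHAF1B (-2.09 ± 0.33, adjusted p = 0.180), ABHD1, within background in all 4 groups, NEFM (-2.31 ± 0.44) and MSANTD4 (-1.47 ± 0.30). HPSE, CYP4F11, B3GNT5, CHAF1B and NEFM had at least 1 group within background. For the genes named beforehand the difference was -1.94 ± 1.12 for IL2, 2.37 ± 0.95 for MX1, -0.84 ± 0.47 for IL2RA, -0.63 ± 0.42 for SAE1, -0.07 ± 0.26 for SUMO2 and -0.20 ± 0.39 for SUMO3. It was -1.51 ± 2.26 for IFNG, 0.15 ± 0.33 for CD69, -0.14 ± 0.44 for MYC, -0.56 ± 0.47 for FOXP3, -0.28 ± 0.59 for TBX21 and -0.48 ± 0.38 for GATA3; MKI67 and IFNB1 lay within background.

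Of 42 lists 6 passed for the difference, and 10 with the donor as a block. Beside interferon-stimulated genes, of which 8 were higher adjusted over the list alone (adjusted p = 1.21e-13, and adjusted p = 0.463 with an estimated correlation), they were ribosome biogenesis (mean -0.51, adjusted p = 4.63e-05), cytokines (-0.75, 0.00752), amino acid stress (-0.42, 0.00543), glycolysis (-0.24, 0.0473) and DNA replication (-0.37, 0.0473). The adjusted p with an estimated correlation was 0.463 for ribosome biogenesis, cytokines, amino acid stress and glycolysis and 0.567 for DNA replication. Cytokines had a mean of -0.42 (adjusted p = 0.147) without replicate 4 of the DMSO arrays at 24 h and -0.55 (0.0594) without replicate 4 of the TAK-981 arrays at 3 h. The DNA replication call was lost without any 1 of 8 arrays: replicates 1 and 3 of DMSO at 3 h, 1 and 4 of TAK-981 at 3 h, 1 and 2 of DMSO at 24 h, and 3 and 4 of TAK-981 at 24 h (adjusted p from 0.0625 to 0.332). Its mean was -0.21 without replicate 1 of DMSO and -0.22 without replicate 3 of TAK-981 at 24 h. The glycolysis call was lost without any 1 of 10: replicates 1, 3 and 4 of DMSO at 3 h, 2 and 4 of TAK-981 at 3 h, 1, 2 and 3 of DMSO at 24 h, and 3 and 4 of TAK-981 at 24 h (0.0575 to 0.114). The most abundant members did not pass: IFITM1 0.37 ± 0.34, IFITM3 0.28 ± 0.27, NPM1 -0.24 ± 0.23, GAPDH 0.03 ± 0.29, PCNA -0.56 ± 0.53 and LTB -0.75 ± 0.41.

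The effects of TAK-981 at 3 h and at 24 h were compared across clusters. NEFM, the 1 call at 3 h, lay within background in both groups at 24 h and was not called there, so 0 clusters passed at both times, where at most 1 was possible. Of the 17 clusters called at 24 h, 14 had the same sign at 3 h. At an unadjusted p below 0.05, 69 clusters were higher at both times where independent lists share 21.1 (Fisher's exact test, two-sided, odds ratio 3.82, p = 3.76e-18), and 51 were lower at both where 21.3 would be shared (odds ratio 2.64, p = 8.32e-09). Log2 fold changes at 3 h and 24 h correlated across clusters with r = 0.107 and rho = 0.0781, and with r = 0.111 and 0.0371 when the 2 times came from different donors. Clusters are not independent, so these p values overstate the evidence.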

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

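Beside the splits of the arrays and the test of a mixture of cells, the tests of the 3 patterns weighed here were chosen after the results were seen. Of 351 groups of 4 arrays checked for an array far from the other 3, 17 passed the 5% critical value of Dixon's gap, where chance gives 17.55, so the count as a whole lies no higher than chance.

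On the first principal component replicate 3 of the TAK-981 arrays at 24 h lay far below the other 3, with a gap of 0.901 of the group's range. The same array was lowest on the time axis defined under DMSO, with a gap of 0.849. For the mean of amino acid stress genes replicate 4 of that group stood apart, above the others (0.965), and for glycolysis replicate 2 of the DMSO arrays at 3 h did, also above (0.86). Single genes with 1 array apart among the DMSO arrays at 3 h were FOXP3 (0.924), TBX21 (0.849), MT1E (0.939), PGK1 (0.995) and PCNA (0.856). Among the DMSO arrays at 24 h they were MX1 (0.92), TRIM22 (0.907), NEFM (0.882), H2AC11 (0.838), ZFP36 (0.832) and IFIT3 (0.83). IL4R had a gap of 0.843 under TAK-981 at 24 h and IFIT3 one of 0.831 under TAK-981 at 3 h.

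The effect of TAK-981 differed between 3 h and 24 h for 6 gene lists by the camera test of the interaction. The adjusted p was 1.21e-13 for interferon-stimulated genes, 4.63e-05 for ribosome biogenesis, 0.00543 for amino acid stress, 0.00752 for cytokines and 0.0473 for both glycolysis and DNA replication. With an estimated correlation each had an adjusted p of at least 0.463, and the calls of cytokines, DNA replication and glycolysis were lost without 2, 8 and 10 of the 16 arrays, each left out alone.

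Each comparison was set against all 35 splits of its 8 arrays, or of the donor differences for the interaction, into groups of 4. These splits move arrays without regard to the donors that pair them, so a share of 1 in 35 does not exclude chance. For the count of genes at 24 h 1 split of 35, the real one, gave 17 and the highest other gave 4. The same held for time under DMSO (1 split, 2706 genes, highest other 3) and under TAK-981 (1 split, 1589 genes, highest other 1). At 3 h chance was not excluded by the count of genes, since 5 splits gave 1 or more and the highest other gave 184; that split kept each donor's arrays together and so follows the donors, while 0 genes was the highest of the other splits that parted all pairs. For the interaction all 35 splits gave 0 genes. For gene lists the real split had the most for time under TAK-981 (1 split, 17 lists, highest other 14). The real split also had the most for the interaction in a model of donor differences (1 split, 11 lists, highest other 6). The main fit passed 6 lists for the interaction and was not split, so those 6 were not weighed. Other splits gave as many lists as the real one at 3 h (19 splits, 2 lists, highest other 6) and at 24 h (8 splits, 9 lists, highest other 13). The same held for time under DMSO (2 splits, 16 lists, highest other 17). Among the 8 splits that part all 4 donors, as the real ones do, the real one had the most lists in each comparison. The highest others there were 1 at 3 h, 6 at 24 h, 14 for time under DMSO, 13 under TAK-981 and 6 for the interaction. For genes as for lists, 8 splits are too few for a share under 0.05, so chance cannot be excluded with donors paired.

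As a group, interferon-stimulated genes had higher values under TAK-981 at 24 h, with a list mean of 1.03, a call that had adjusted p = 0.167 with an estimated correlation. RNA from monocytes, dendritic cells or B cells would raise the abundant transcripts of those cells. The higher of their marker list means was 0.0435. The sort gate was CD4+CD45RA+CD45RO-, and how far it kept such cells out was not tested. A mean over a whole list can hide a rise in a few members, so such RNA is not excluded. The most abundant markers, all of the B cell list, were FCMR at 12.53 under TAK-981 and 11.95 under DMSO (0.585 ± 0.324), FCRLA at 7.76 and 7.72, and CD79A at 7.38 and 7.46. A single donor did not carry the shift alone, since without the donor of the largest shift the mean was 0.719 with an SD of 0.574. The donors ranged from 0.31 to 1.96, and the shift was uneven. List means under TAK-981 at 24 h were 10.38 and 9.65 in replicates 2 and 4, and 8.66 and 8.65 in replicates 1 and 3. The DMSO arrays at 24 h had 8.18 to 8.42. Beside RNA of other cells, an effect of the compound, an inhibitor of SUMO activation, on interferon signalling stays open as a candidate. No test here separates it from other effects of TAK-981.

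TAK-981 arrays at 24 h lay less far along the time axis defined under DMSO, at 0.773 ± 0.119 against 0.940 ± 0.037. On this axis 0 and 1 are the means of the other donors' DMSO arrays at 3 h and 24 h. Without regard to donors the exact permutation p was 0.0286, the smallest 4 against 4 arrays can give. An exact two-sided sign-flip test of 4 donor pairs allows no p below 0.125. At 3 h the positions were 0.117 and 0.118 (exact permutation p = 0.971), and at 24 h the lowest array does not account for the difference, since the other 3 averaged 0.832, each below every DMSO array. Weaker signal of the TAK-981 arrays cannot be told apart, since RMA makes the signal distributions alike and so leaves the difference of interquartile ranges (-0.0296) without meaning. A share of cells still in the 3 h state, 0.371 from the rising genes, would keep falling genes 2.00 higher, and they were 0.43 higher, -1.57 ± 0.25 from that value (SD over 4 donors). That estimate covers only cells held in the 3 h state, and other mixtures of cells were not tested. A slower gain of late transcripts under TAK-981 may explain the positions, and it stays open beside weaker signal and such mixtures.

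Some genes higher under TAK-981 at 24 h were neighbours in the genome. Among 83 genes with an unadjusted p below 0.001 in the fit with the donor as a block, 9 pairs lay within 3 genes of each other where 1.23 were expected, and the share of 10000 random sets matched on level with as many was 1e-04, the smallest they can give. Without the interferon list and with 1 gene per name stem 5 pairs were left among 72 genes (0.933 expected, share 0.0024), so gene families and interferon genes such as IFI44L and IFI44 account for part only; the 5 were NID1 with GPR137B and GPR137B with ERO1B, which form 1 run of 3 adjacent genes, CNN2 with ABCA7, CYP4F11 with TPM4 and PDGFA with SUN1. Among as many genes rising with time under DMSO 4 pairs were found (1.32 expected), so a general likeness of neighbours in these arrays cannot be told apart from an effect of the compound with these counts. Local opening of chromatin or transcription running on into the next gene could each give such pairs, and neither was tested.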

How the results depend on the processing

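Chosen after seeing the data were the fits without replicate 3 of the TAK-981 arrays at 24 h for lists or together with the donor block, the correlation estimated with the block, and single lists without each array or under the settings used for genes. Most array signals were low (12055 of 21352 clusters had a mean within background), which limits what dim genes can show. The count at 24 h, 17, was 41 with the replicate block, 26 with the donor as a random effect, 29 with array weights, 0 with only the compared arrays (limma; 1416 at an unadjusted p below 0.05 in the full fit), 350 at an unadjusted p with a 2-fold change and 7 without replicate 3 with the block. It was 0 to 3 without a replicate number and 0 to 26 without an array. The count at 3 h, 1, was 254 at an unadjusted p with a 2-fold change, 2 without that array with the block, 1 to 2 without a replicate number and 1 to 3 without an array. Time under DMSO gave 1674 to 2743 calls and under TAK-981 706 to 1687 with a replicate or array left out. The interaction gave 589 at an unadjusted p with a 2-fold change, 1 without that array with the block, 0 without any replicate number and 0 to 1 without an array; it uses all groups, so a fit of only the compared arrays has no separate value.

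List counts fell with an estimated correlation to 0 at 3 h, 0 at 24 h, 5 for time under DMSO, 2 under TAK-981 and 0 for the interaction, and with the block as well to 0, 0, 5, 6 and 0. A correlation of 0.05 gave 0, 5 and 2 lists for 3 h, 24 h and the interaction, and fry gave 1, 2 and 0. At 3 h 0 lists passed without the 40% of clusters of lowest level. The interaction passed 10 lists with the block and 3 to 6 without a replicate. At 24 h the naive list had adjusted p = 0.0549 and Th2 0.158 without replicate 2, and T cell identity 0.167 and glycolysis 0.0721 without replicate 3. The correlation of effects at 3 h and 24 h was 0.137 and 0.117 without the lowest 40% and 20%, and 0.0741 to 0.108 without a replicate. Of 4427 values of named calls under alternatives 335 lost the call and 0 reversed, 52 other values gained one, and 98 values changed sign where neither value passed. Those started from at most 0.42 in size, and the largest went to 0.85 (IL2 at 3 h without replicate 3 of the TAK-981 arrays). The pooled share of lost calls hides weaker calls for TAK-981 at 24 h. Among those 17 genes the call was lost under between 5 of 30 settings (CYP4F11) and 15 of 31 (AFDN). HERC5 lost it under 10 of 31, CHAF1B under 11 and CKS2 under 13. The block ended the call of ADAR for time under DMSO (0.68, adjusted p = 0.0383, and 0.0564 with the block) and changed no other named call beyond those printed with it. With the donor as a random effect ZFP36 passed at 24 h (adjusted p = 0.0439). Except where fewer arrays or clusters were used, the cause was not tested.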

Other observations

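The single genes named in this part were chosen after their values were seen, and no hypothesis was tested with them. The gene lists given below them were chosen before the data were examined and were tested with camera like the other lists. Several genes passed at 24 h with the donor as a replicate block and not without it. Higher under TAK-981 were ANXA1, an anti-inflammatory phospholipid-binding protein (2.45 ± 0.59, adjusted p with the block 0.0031), IFI44, an interferon-stimulated gene (2.36 ± 0.54, 0.0118), ATF7IP, a partner of the histone methyltransferase SETDB1 (1.88 ± 0.35, 0.0217), and RESF1, a retroelement silencing factor (1.20 ± 0.27, 0.0378). TRIM22, an interferon-induced ubiquitin ligase (1.49 ± 0.41, 0.0235), CH25H, the cholesterol 25-hydroxylase (within background in both groups, 0.0293), and BTN3A2, a butyrophilin (1.42 ± 0.31, 0.0418), were higher too. SLAMF1, a costimulatory receptor, was lower (-2.79 ± 0.71, 0.0378). ZFP36, which promotes decay of cytokine mRNA, had 1.11 ± 0.21 and passed in neither of these fits (adjusted p = 0.0604, and 0.0516 with the block).

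The 20 measured interferon ligand genes had a mean of -0.11 at 24 h and did not pass as a list (camera adjusted p = 0.349), and 19 of them lay within background. Zinc finger genes (493 measured) had a mean of 0.10 (adjusted p = 0.120), replication-dependent histones 0.05 (0.466), germline genes 0.05 (0.503) and PML nuclear body genes 0.18 (0.204). The interferon-gamma response list had 0.14 (0.156).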
